A study of Homo sapiens with 24 samples.

How the data were processed

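The data were gene counts of 24 RNA-seq libraries of H1 cells, an established line of human embryonic stem cells, in 8 groups of 3 libraries. Per the labels' protocols, the cells grew in mTeSR1, a defined stem cell medium, on matrigel, a basement membrane extract. In 7 groups a lentivirus carried 1 overexpressed gene into the cells: BARHL1, IRX3, LHX5, OTX1, OTX2, PAX6, or EGFP, the green fluorescent protein that served as control. The group called dSi here held cells taken towards neural progenitors by dual-Smad inhibition, a block of BMP and of activin and nodal signalling, for 72 hours. These cells then grew for 72 hours in N2B27, a neural medium, with FGF and EGF, and the labels name no infection for them. RNA was taken with a column kit and a service provider enriched mRNA and made the libraries. The labels differ on the time between infection and harvest, which one field gives as 14 days and another as 14 hours, so no time is attached to any value.

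The authors deposited raw read counts per gene symbol, not normalized, with 1 column per library. Per the submitters' processing notes, Trimmomatic 0.3.2, TopHat2 2.1.1, Cufflinks, Picard, SAMtools 1.3.1 and featureCounts 1.5.0-p3 were used with the hg19 build of the human genome, with no order or role given. The gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Counts of a gene and of an antisense gene that overlaps it cannot therefore be separated, and counts of genes with near-identical copies, such as the pseudogenes of POU5F1, NANOG and TDGF1 and those of many ribosomal protein genes, are uncertain. Of the 35895 rows of the deposited table, 5980 were numbered copies of 2209 symbols, and for 793 of these symbols all copies held the same counts. Copies held 5.96 to 6.70% of a library's counts. The copy with the highest total was kept for each symbol, which left 32124 symbols. A further 26 names had been turned into dates by a spreadsheet and are not named in the text.

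All tests on counts used edgeR 4.0.16 in R 4.3.3, with limma 3.58.1. Genes were kept by filterByExpr with a minimum count of 10, which left 17534 genes, and libraries were scaled by TMM factors. A quasi-likelihood model with 1 coefficient per group was fitted to all 24 libraries, so that every comparison shared 1 estimate of the spread with 16 residual degrees of freedom. The common dispersion of 0.00823 corresponded to a coefficient of variation of 9.07% between libraries of a group. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p below 0.05 are called changed. A second count asked also for a change of at least 2-fold. The overexpressed genes were left out of the counts of their own comparisons, since counts of the transgene and of the endogenous gene cannot be told apart. Levels are CPM (counts scaled to a common library total of 1e+06) on TMM-scaled library sizes, given as the mean ± SD of the 3 libraries of a group, and changes are log2 fold changes ± SE against EGFP unless another group is named. Where a group held no count of a gene, the fold is a lower bound set against a floor of 3 counts over the group, and where it held 1 to 3 counts, the ratio of counts is given with its 95% counting interval in place of a fitted change. Floors and intervals cover counting error only.

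Each factor and dSi were compared with EGFP, OTX2 with OTX1, the mean of the 6 factors with EGFP, and the 6 factors with each other by an F test. For 25 gene lists the number of members that rose or fell was counted, both after adjustment over all genes and adjusted over the list alone, and camera tested each list in 8 comparisons with a preset correlation of 0.01 between genes. The lists held markers of pluripotency, naive pluripotency, neural progenitors, forebrain, midbrain and hindbrain, neurons, glia, neural crest and placodes, retina and pigment cells, primitive streak and mesoderm, endoderm, amnion and trophoblast, surface ectoderm, and mesenchyme and matrix. The others held targets or members of the nodal, BMP, WNT, FGF-ERK, notch, interferon and p53 pathways, of the integrated stress response, and of proliferation, hypoxia and glycolysis, and cholesterol synthesis. Some lists share members, so their calls are not separate evidence. TDGF1, GDF3 and FOXH1 are in both the pluripotency and the nodal list, and MSX1, MSX2 and DLX5 in both the neural crest and the BMP list. Calls of genes shared by a factor and dSi were counted per direction beside the overlap of independent lists, and correlations of changes were set beside 10 simulations of unchanged groups against the same EGFP libraries. These groups were drawn around the mean of the same EGFP libraries, so the error of that mean is left out. The text names, in each comparison, the overexpressed gene, the 10 risen and 10 fallen genes with the largest change among called genes whose mean log2 CPM was at least 1 and whose libraries did not overlap between the groups, up to 4 members with the smallest adjusted p of each called list, and a panel of 19 marker genes. The lists, tests, naming rule and alternatives were fixed before the data were examined, except where the text says otherwise. Some genes that this rule selects are not reported here. Genes whose symbol is a clone, antisense, small RNA or date name are left unnamed, and EMX2 lies partly opposite the antisense gene EMX2OS, so that its counts are uncertain.

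The deposited totals ran from 19.5 to 25.3 M counts per library. On simulated counts with the means of EGFP and the library sizes of LHX5 and EGFP over 16329 genes, all 50 genes changed by 1 on the log2 scale were called (100%), against 50% of those changed by 0.5 and 8% of those changed by 0.25. The changed genes were drawn only from those above a minimum level in EGFP, which SOX1, PAX6 and SIX3, among others, did not reach. Recovery of changes in such weakly expressed genes was not simulated. Of the genes called there, 5.26% were unchanged ones. Every pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 2.06 to 8.68 outside the dSi group, so none was treated as a copy of another. The labels call the 3 libraries of a group replicates and do not say that they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Alternatives were DESeq2 1.42.0, its size factors in the edgeR model, no filter on low counts, a fit of only the groups compared, a replicate block, leaving out each library in turn, and for the lists an estimated correlation. Keeping every row as deposited and summing the copies of a symbol were added after seeing the data. Coordinates are 1-based positions on GRCh37, the same assembly as hg19, from the GENCODE annotation mapped to that assembly. Of the symbols, 23742 were found in a separate reference of gene names.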

Results

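Gene counts were available for 24 RNA-seq libraries of H1 human embryonic stem cells, 3 for each of 8 groups. The cells of 6 groups overexpressed a transcription factor of early neural development, and those of the EGFP group the fluorescent control protein. The dSi group, neural progenitors made by dual-Smad inhibition, served as the neural reference. The series asks what candidate factors of neural induction do to gene expression in stem cells. Total counts, with M for 1e+06, were 22.0, 20 and 25 M in the BARHL1 libraries, 21.6, 21.0 and 19.6 M in IRX3, 24.4, 21.7 and 23.1 M in LHX5, and 20.1, 23.3 and 22.3 M in OTX1. They were 20.1, 20.2 and 22.5 M in OTX2, 19.5, 20.5 and 22.9 M in PAX6, 21.6, 25.3 and 21.2 M in EGFP, and 23.4, 24.2 and 22.4 M in dSi. Levels are in CPM with n = 3 libraries per group throughout.

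The overexpressed gene was higher than in EGFP in all 6 groups. BARHL1 (chromosome 9, 135457993 to 135465639, plus strand), a homeobox gene of hindbrain and diencephalon, stood at 46.3 ± 2.14 CPM in its own libraries and at 0.0762 ± 0.0728 CPM in EGFP, a log2 change of 9.12 ± 0.29. IRX3 (chromosome 16, 54317216 to 54320699, minus strand), an Iroquois gene of the caudal neural plate, stood at 456 ± 13.2 against 3.69 ± 0.275 CPM (6.95 ± 0.18). LHX5 (chromosome 12, 113899838 to 113910085, minus strand), a LIM-homeobox gene of the anterior neural plate, reached 555 ± 12.4 against 1.68 ± 0.156 CPM (8.36 ± 0.13). OTX1 (chromosome 2, 63277192 to 63284971, plus strand), a homeobox gene of forebrain and midbrain, reached 103 ± 2.88 against 3.14 ± 0.197 CPM (5.03 ± 0.12). PAX6 (chromosome 11, 31806327 to 31839509, minus strand), a paired-box gene of neural progenitors and the eye, reached 77.0 ± 1.65 against 1.18 ± 0.381 CPM (6.04 ± 0.17). OTX2 (chromosome 14, 57266623 to 57283411, minus strand), the paralogue of OTX1, was already present in EGFP cells at 61.5 ± 4.06 CPM and stood at 111 ± 5.11 CPM in its own libraries (0.85 ± 0.07). In the OTX1 libraries OTX2 stood at 117 ± 4.78 CPM, and the difference of OTX2 between these groups was not called (-0.08 ± 0.07, edgeR adjusted p = 0.426). All 6 are protein-coding genes, and their counts do not separate the introduced copy from the cell's own gene.

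**Figure D1:**
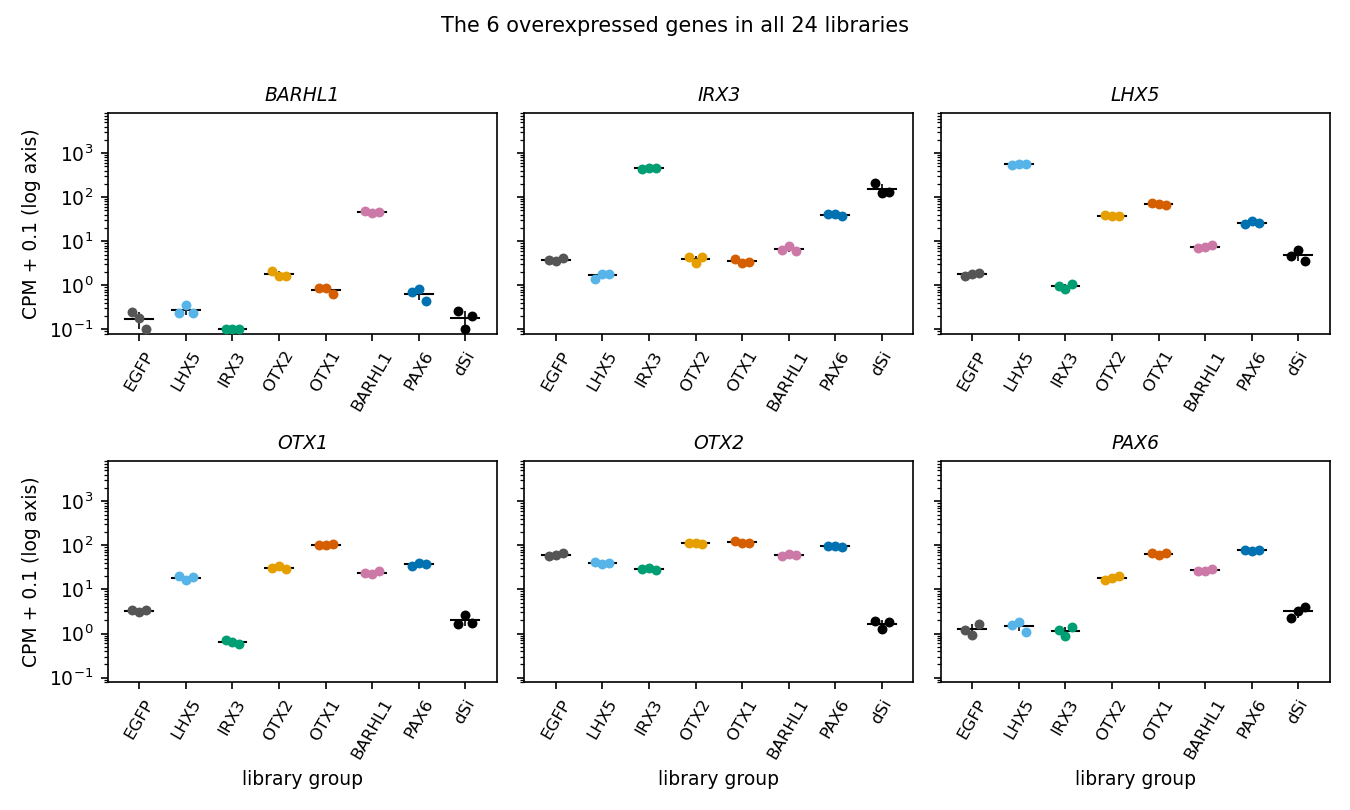
Levels of the 6 overexpressed genes in all 24 libraries, on a log axis of CPM plus 0.1, by group. Points are libraries, horizontal bars group means and vertical lines ± SD. Each gene is high in its own group, while OTX2 stands at 111 CPM in its own and 117 CPM in the OTX1 libraries.

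The number of changed genes differed widely between the factors. Against EGFP, 5693 of 17533 genes changed in LHX5, 9688 in IRX3, 10510 in OTX2, 11770 in OTX1, 12354 in BARHL1 and 12646 in PAX6. In dSi, 12470 of 17534 genes changed. With a change of at least 2-fold as well, the numbers were 1403 in LHX5, 3368 in IRX3, 4153 in OTX2, 5311 in OTX1, 5613 in BARHL1, 6171 in PAX6 and 5968 in dSi. On the first principal component, which held 46.1% of the variance, the LHX5 libraries lay at 102 to 107 beside EGFP at 119.6 to 120.1, and the PAX6 libraries at -71.7 to -70.9 beside dSi at -80.4 to -74.1. For each list whose counts are given, those adjusted over the list alone follow where they differ from those adjusted over all genes. Of the 25 lists, glia and interferon were not called in any of the 8 comparisons. The lowest adjusted p of the glia list was in IRX3, where 7 of 10 rose and 2 fell (camera adjusted p = 0.102, not called), and that of the interferon list in PAX6, where 3 of 14 rose and 6 fell (camera adjusted p = 0.285, not called). Where a list was called but its median change, mean change and test differed in sign, the text says so.

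**Figure D2:**
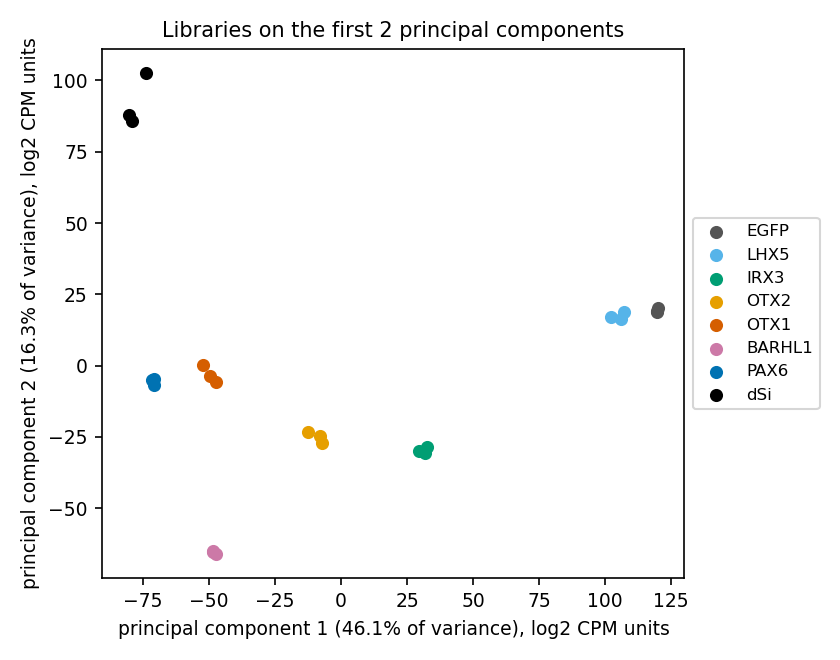
The 24 libraries on the first and second principal components of log2 CPM, which hold 46.1% and 16.3% of the variance, with colours for the 8 groups. EGFP and LHX5 libraries lie at the right end of the first component and PAX6 and dSi at the left, and dSi stands apart on the second.

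LHX5 raised RIPPLY3 (chromosome 21, 38378450 to 38391962, plus strand), a corepressor that works with T-box factors, from 4.33 ± 0.929 to 1309 ± 24.1 CPM (8.25 ± 0.17), the largest rise after that of LHX5 itself among the genes named by the rule. DPPA3, a factor of the germ line and of naive pluripotency, rose from 0.996 ± 0.222 to 219 ± 1.63 CPM (7.77 ± 0.20). The sortilin-family receptor SORCS2 (6.09), the LIM-only gene LMO1 (5.19), GAD1, which makes the transmitter GABA (4.84), and CYP26A1, which degrades retinoic acid (4.42), were among the other large rises. The largest falls were those of NPTX1 (chromosome 17, 78440634 to 78451643, minus strand), a neuronal pentraxin, from 461 ± 69 to 3.88 ± 1.18 CPM (-6.90 ± 0.18), of CUZD1 (-5.40 ± 0.19) and of RAB17, a small GTPase of epithelia (-4.51 ± 0.16).

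The pluripotency list went both ways, since 8 of 20 rose and 8 fell, or 9 and 9 adjusted over the list alone (camera adjusted p = 0.370, not called). POU5F1 (chromosome 6, 31132114 to 31148508, minus strand), a core factor of pluripotency, stood at 1253 ± 21.3 against 1132 ± 18.5 CPM and was not called (0.15 ± 0.06, adjusted p = 0.0671), but it was with only the compared groups in the fit (adjusted p = 0.00252) and with copies summed (0.0120), in a range over all alternatives of 0.00252 to 0.162. NANOG (chromosome 12, 7940390 to 7951742, plus strand), another core factor, rose (1.05 ± 0.10), while SOX2, shared by stem cells and neural progenitors, fell (-1.14 ± 0.06), as did TDGF1, the coreceptor of nodal (-1.31 ± 0.08). In the naive list, 3 of 10 rose and 2 fell (camera adjusted p = 0.000729), with a mean of 0.72 and a median of -0.23. This call was lost with the replicate number as a block (adjusted p = 0.0627), and the risen members included DPPA3 and the nuclear receptor ESRRB (1.99 ± 0.33). Among the forebrain genes 10 of 12 rose and 1 fell (camera adjusted p = 7.48e-08), among them HESX1, a repressor of the anterior neural plate (3.74 ± 0.18), LHX2 (2.79 ± 0.20), OTX1 (2.55 ± 0.12) and EMX2 (4.54 ± 0.48). For the neural progenitor genes, 13 of 20 rose and 3 fell (camera adjusted p = 0.000508), with CDH2, the neural cadherin, at 1.95 ± 0.08 and DLK1 at 3.07 ± 0.13. SOX1, an early neural marker, was near the floor in both groups, at 0.286 ± 0.111 and 0.274 ± 0.0690 CPM, and PAX6 stood at 1.41 ± 0.385 and 1.18 ± 0.381 CPM, and neither was called (adjusted p = 0.989 and 0.457). Of the neuron genes 8 of 22 rose and 1 fell (camera adjusted p = 3.67e-05), including STMN2, a microtubule regulator of growing axons (3.71 ± 0.13), and the neurofilament genes NEFL (1.31 ± 0.07) and NEFM (1.09 ± 0.05).

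Targets of some signalling pathways changed in the LHX5 libraries as well. Among the FGF-ERK feedback genes 12 of 15 rose and 2 fell (camera adjusted p = 2.93e-34), led by DUSP6, a phosphatase of ERK, at 559.7 ± 6.41 against 45.7 ± 3.91 CPM (3.61 ± 0.06). For the nodal targets, 8 of 11 rose and 1 fell (camera adjusted p = 9.73e-09), with SMAD7 at 3.12 ± 0.08 and GDF3 at 2.34 ± 0.12. Of the BMP targets 5 of 13 rose and 2 fell (camera adjusted p = 2.27e-06); ID4 rose (3.18 ± 0.09) and ID1 fell (-1.27 ± 0.16). All cholesterol synthesis genes went up, in that 15 of 15 rose and 0 fell (camera adjusted p = 4.37e-19). Of the p53 targets 3 of 19 rose and 12 fell, or 3 and 14 adjusted over the list alone (camera adjusted p = 0.00107), including the death receptor gene FAS (-3.75 ± 0.25) and the cell cycle inhibitor CDKN1A (-0.97 ± 0.14). Among the hypoxia and glycolysis genes 7 of 16 rose and 0 fell, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.0373, but adjusted p = 0.425 with an estimated correlation). For the neural crest and placode genes, 8 of 17 rose and 2 fell (camera adjusted p = 0.00196), with SOX9 at 1.42 ± 0.09. The midbrain and hindbrain list was not called, since 6 of 20 rose and 2 fell, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.102, not called), nor was the endoderm list, since 4 of 14 rose and 0 fell (camera adjusted p = 0.232, not called).

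IRX3 raised genes of the midbrain and hindbrain. EN2 (chromosome 7, 155250824 to 155257526, plus strand), a marker of the midbrain-hindbrain boundary, stood at 170.5 ± 7.77 CPM against 0.0165 ± 0.0286 CPM in EGFP, a ratio of counts of 11039-fold (95% counting interval 1981 to 436062). GBX2, which sets the anterior limit of the hindbrain, rose from 0.507 ± 0.258 to 124 ± 8.36 CPM (7.95 ± 0.16), PAX8 from 0.107 ± 0.0157 to 124 ± 8.52 CPM (10.09 ± 0.20) and PAX5 from 0.677 ± 0.291 to 66.8 ± 0.644 CPM (6.58 ± 0.22). The forebrain repressor FEZF1 fell from 22.3 ± 1.46 to 0.128 ± 0.0696 CPM (-7.36 ± 0.29). Other large falls were those of NPTX1 (-7.01 ± 0.19), CUZD1 (-6.26 ± 0.21) and IDO1, an enzyme of tryptophan breakdown (-4.85 ± 0.15).

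Of the midbrain and hindbrain genes 16 of 19 rose and 2 fell (camera adjusted p = 7.69e-18), whereas of the forebrain genes 1 of 13 rose and 7 fell (camera adjusted p = 0.00692, but adjusted p = 0.0729 with an estimated correlation), with falls of OTX1 (-2.53 ± 0.22), OTX2 (-1.07 ± 0.07) and RAX (-2.07 ± 0.26). Among the neural progenitor genes 14 of 20 rose and 2 fell (camera adjusted p = 6.31e-24), including the orphan receptor gene NR2F1 (chromosome 5, 92918928 to 92930317, plus strand) at 112 ± 5.61 against 0.0466 ± 0.00426 CPM, POU3F2 (8.15 ± 0.17) and SOX1 (7.48 ± 0.17). PAX6 was not called at 1.06 ± 0.263 CPM (-0.13 ± 0.28, adjusted p = 0.714). For the neuron genes, 15 of 22 rose and 2 fell, or 16 and 2 adjusted over the list alone (camera adjusted p = 1.71e-09), with NEFM at 2.54 ± 0.06. Of the pluripotency genes 2 of 20 rose and 16 fell (camera adjusted p = 2.54e-15); POU5F1 fell (-0.82 ± 0.06) and NANOG rose (0.52 ± 0.10). Genes of other germ layers rose too: of the endoderm list 11 of 14 rose and 1 fell (camera adjusted p = 1.11e-14), with CER1, a secreted nodal and BMP antagonist, at 104 ± 7.99 against 0.0327 ± 0.0283 CPM and SOX17 (chromosome 8, 55370495 to 55373452, plus strand) at 24.7 ± 0.333 against 0.0165 ± 0.0286 CPM. In the primitive streak list, 7 of 13 rose and 0 fell (camera adjusted p = 5.41e-09), with EOMES at 7.83 ± 0.32. In the neural crest and placode list, 13 of 17 rose and 2 fell, or 14 and 2 adjusted over the list alone (camera adjusted p = 5.08e-15), with SOX9 at 3.28 ± 0.09. The mesenchyme and matrix list also rose, in that 16 of 18 rose and 1 fell (camera adjusted p = 3.97e-18), and COL3A1 (chromosome 2, 189839099 to 189877472, plus strand), a fibrillar collagen with 0 counts in EGFP, reached 178 ± 0.981 CPM, at least 3849-fold higher.

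Of the 7 pathway lists, those of nodal, BMP and WNT targets, FGF-ERK feedback and notch rose in IRX3 against other genes, while interferon (camera adjusted p = 0.853) and p53 (0.145) were not called. Of the FGF-ERK feedback genes 14 of 15 rose and 1 fell (camera adjusted p = 2.59e-23). Among the WNT targets 11 of 13 rose and 1 fell (camera adjusted p = 2.58e-16). For the nodal targets, 9 of 11 rose and 2 fell (camera adjusted p = 7.8e-06). Of the BMP targets 10 of 13 rose and 1 fell, or 11 and 1 adjusted over the list alone (camera adjusted p = 8.17e-07). Among the notch genes 11 of 14 rose and 1 fell (camera adjusted p = 0.00310). DUSP6 stood at 488 ± 13.3 CPM, the nuclear WNT effector LEF1 at 5.34 ± 0.11 and NODAL at 4.64 ± 0.18, while ID1 fell (-1.86 ± 0.17). Cholesterol genes rose, in that 13 of 15 rose and 0 fell (camera adjusted p = 1.92e-06). For the integrated stress genes, 2 of 15 rose and 9 fell (camera adjusted p = 0.00597, but adjusted p = 0.302 with an estimated correlation), among them CHAC1 (-2.50 ± 0.18). The fall of LHX2, at 0.333 ± 0.236 against 0.590 ± 0.198 CPM, was lost without IRX3 replicate 1 (adjusted p = 0.397) or replicate 2 (0.0735) and without EGFP replicate 1 (0.0613) or replicate 2 (0.289). This LHX2 call was also lost with only the compared groups in the fit (adjusted p = 0.132) and without the low-count filter (0.0552), and over all alternatives adjusted p ran from 0.00586 to 0.397.

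OTX2 raised genes of the primitive streak and also genes of the neural plate. EOMES, a T-box gene of the streak, rose from 0.135 ± 0.0638 to 144 ± 16.1 CPM (9.96 ± 0.29), MIXL1, a homeobox gene of the streak, from 0.589 ± 0.0438 to 222 ± 16.4 CPM (8.55 ± 0.24), and T, the brachyury gene, from 0.233 ± 0.225 to 42.4 ± 3.42 CPM (7.48 ± 0.32). CER1 stood at 84.9 ± 7.62 CPM in OTX2. ZIC1, a zinc finger gene of the neural plate, rose from 1.25 ± 0.219 to 122 ± 5.24 CPM (6.58 ± 0.18), and LGI1, a secreted neuronal protein gene, from 0.080 ± 0.105 to 74.4 ± 1.95 CPM (9.81 ± 0.23). NPTX1 fell to 0.699 ± 0.312 CPM (-9.37 ± 0.23) and GPR176, an orphan receptor gene, from 371 ± 11.3 to 5.40 ± 0.521 CPM (-6.10 ± 0.10).

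In the primitive streak list, 8 of 13 rose and 1 fell (camera adjusted p = 4.95e-10). In the endoderm list, 11 of 14 rose and 1 fell, or 11 and 2 adjusted over the list alone (camera adjusted p = 1.08e-09), with SOX17 at 15.2 ± 2.38 CPM and GATA6, an endoderm factor, at 18.2 ± 0.851 against 0.0443 ± 0.0419 CPM. For the neural progenitor genes, 15 of 20 rose and 4 fell (camera adjusted p = 1.46e-18), with SOX1 at 5.26 ± 0.20 and PAX6 at 3.96 ± 0.18. Of the forebrain genes 10 of 12 rose and 2 fell (camera adjusted p = 3.06e-13), with EMX2 at 9.80 ± 0.26 and SIX3 at 2.53 ± 0.17. Among the midbrain and hindbrain genes 17 of 20 rose and 2 fell (camera adjusted p = 1.84e-23), with GBX2 at 6.79 ± 0.16. For the neuron genes, 14 of 22 rose and 5 fell, or 15 and 5 adjusted over the list alone (camera adjusted p = 0.0309, but adjusted p = 0.0922 with an estimated correlation), and TUBB3, a neuronal tubulin gene, fell (-0.85 ± 0.10). Of the pluripotency genes 2 of 20 rose and 17 fell (camera adjusted p = 3.64e-13), with TERF1 at -2.32 ± 0.05 and POU5F1 at -1.20 ± 0.06, but NANOG rose (1.07 ± 0.10). Among the neural crest and placode genes 10 of 17 rose and 4 fell (camera adjusted p = 3.32e-08), with PAX3 at 39.7 ± 0.705 against 0.0139 ± 0.0241 CPM. In the mesenchyme list, 13 of 18 rose and 4 fell (camera adjusted p = 0.000203). The WNT targets rose, in that 12 of 13 rose and 0 fell (camera adjusted p = 1.59e-24), led by SP5 (7.45 ± 0.18) and DKK1 (8.69 ± 0.22). Of the nodal targets 8 of 11 rose and 2 fell (camera adjusted p = 0.0001). Among the BMP targets 10 of 13 rose and 1 fell (camera adjusted p = 3.34e-08). For the FGF-ERK genes, 13 of 15 rose and 0 fell (camera adjusted p = 2.23e-14). Of the notch genes 7 of 14 rose and 3 fell (camera adjusted p = 0.0309). Among the cholesterol genes 13 of 15 rose and 1 fell (camera adjusted p = 0.00330). For the hypoxia and glycolysis genes, 2 of 16 rose and 12 fell, or 2 and 13 adjusted over the list alone (camera adjusted p = 0.00823, but adjusted p = 0.299 with an estimated correlation). The small fall of ID1 (-0.39 ± 0.15) was lost on leaving out any single EGFP or OTX2 library, with adjusted p from 0.0511 to 0.0981, and the lowest of its other alternatives was 1.81e-06. Its levels did not overlap, at 34.3 to 37.4 CPM in OTX2 and 46.4 to 49.4 CPM in EGFP. The spread in this test is shared by all groups, dSi included.

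Among the largest rises with OTX1 were genes of the dorsal forebrain and of WNT signalling. EMX2 (chromosome 10, 119301956 to 119309057, plus strand), a homeobox gene of the cortical primordium, rose from 0.0657 ± 0.0759 to 173 ± 4.24 CPM (11.32 ± 0.25), and DMRTA2, another gene of the cortical primordium, from 0.0913 ± 0.0799 to 111 ± 11 CPM (10.14 ± 0.23). DKK1, a secreted WNT antagonist, rose to 108 ± 14.7 CPM (9.71 ± 0.21) and RSPO3, a secreted WNT agonist, to 97.8 ± 3.24 CPM (9.75 ± 0.19). Among the largest falls were those of CUZD1 (-7.72 ± 0.24), NPTX1 (-7.67 ± 0.20), A2ML1, a protease inhibitor gene (-6.53 ± 0.26), and FOXD3, a factor of stem cells and neural crest (-5.71 ± 0.30).

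Of the forebrain genes 10 of 12 rose and 2 fell (camera adjusted p = 1.95e-19), including FEZF2 (8.11 ± 0.20), LHX2 (6.69 ± 0.16), LHX5 (5.37 ± 0.13) and SIX3 (4.81 ± 0.16). Among the retina and pigment genes 8 of 10 rose and 0 fell (camera adjusted p = 0.0464, but adjusted p = 0.0934 with an estimated correlation), among them MITF, the regulator of pigment cells (2.56 ± 0.20), and TYRP1, an enzyme of melanin synthesis (5.09 ± 0.44). For the neural progenitor genes, 15 of 20 rose and 5 fell (camera adjusted p = 1.91e-21), with DLK1 from 2.65 ± 0.309 to 281 ± 20.6 CPM (6.73 ± 0.13) and SOX1 at 6.25 ± 0.19. Of the midbrain and hindbrain genes 16 of 20 rose and 3 fell (camera adjusted p = 1.11e-06). Among the neural crest and placode genes 12 of 17 rose and 4 fell (camera adjusted p = 0.00346), with falls of FOXD3 and SOX10 (-3.33 ± 0.20). For the pluripotency genes, 0 of 20 rose and 18 fell (camera adjusted p = 6.88e-39), with POU5F1 down to 108 ± 3.68 CPM (-3.39 ± 0.07), TDGF1 to 29.6 ± 1.65 CPM (-4.69 ± 0.09) and NANOG to 20.1 ± 1.17 CPM (-1.41 ± 0.10). Of the notch genes 8 of 14 rose and 3 fell (camera adjusted p = 0.00466), with HEY1 at 6.26 ± 0.12 and the ligand DLL1 at 3.27 ± 0.10. Among the WNT targets 11 of 13 rose and 1 fell (camera adjusted p = 1.16e-16). For the BMP targets, 11 of 13 rose and 1 fell (camera adjusted p = 9.97e-06). Of the FGF-ERK genes 10 of 15 rose and 2 fell (camera adjusted p = 2.04e-07). Among the primitive streak genes 8 of 13 rose and 2 fell (camera adjusted p = 0.000818). For the endoderm genes, 9 of 14 rose and 2 fell (camera adjusted p = 0.000691). In the mesenchyme list, 12 of 18 rose and 5 fell (camera adjusted p = 0.00401, but adjusted p = 0.0943 with an estimated correlation). Among the hypoxia and glycolysis genes 1 of 16 rose and 14 fell (camera adjusted p = 4.93e-05, but adjusted p = 0.0943 with an estimated correlation). For the cholesterol genes, 13 of 15 rose and 1 fell (camera adjusted p = 0.0145). The nodal target list was not called, since 7 of 11 rose and 3 fell (camera adjusted p = 0.965, not called).

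BARHL1 raised genes of mesenchyme and of endoderm. COL3A1 reached 989 ± 15.7 CPM, at least 21346-fold above EGFP, and LUM, a matrix proteoglycan gene also without counts in EGFP, reached 72.5 ± 1.56 CPM, at least 1565-fold. CDX2, a caudal and trophoblast homeobox gene, reached 90.1 ± 10.1 CPM (at least 1938-fold), HOXB9, a trunk gene of the HOX clusters, 79.3 ± 16.6 CPM (at least 1699-fold) and PITX1, a hindlimb gene, 61.0 ± 2.25 CPM (at least 1316-fold). SOX17 stood at 39 ± 1.91 CPM, a ratio of counts of 2529-fold (95% counting interval 453 to 99923), and GATA6 at 53 ± 4.02 CPM. The largest falls were those of CUZD1 (-7.62 ± 0.24), NPTX1 (-7.44 ± 0.19), FEZF1 (-6.62 ± 0.26) and IDO1 (-6.31 ± 0.17).

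In the mesenchyme and matrix list, 17 of 18 rose and 1 fell (camera adjusted p = 3.73e-29), with ACTA2, smooth muscle actin, from 2.74 ± 0.379 to 309.6 ± 19.9 CPM (6.82 ± 0.17). All endoderm genes went up, in that 14 of 14 rose and 0 fell (camera adjusted p = 5.84e-17). In the primitive streak list, 9 of 13 rose and 3 fell (camera adjusted p = 7.11e-09), with T at 6.85 ± 0.32. The amnion and trophoblast list was called up, in that 9 of 13 rose and 2 fell (camera adjusted p = 6.47e-05), with HAND1, a mesoderm and amnion gene, at 57.8 ± 3.84 CPM against 0.0496 ± 0.0859 CPM. For the neural crest and placode genes, 13 of 17 rose and 3 fell (camera adjusted p = 1.34e-09), with SNAI2 at 6.83 ± 0.11, MSX1 at 8.86 ± 0.28 and SOX10 at -0.70 ± 0.15. Of the midbrain and hindbrain genes 17 of 19 rose and 1 fell (camera adjusted p = 1.23e-16), with LMX1B, a gene of the roof plate and isthmus, at 6.52 ± 0.16. Among the neural progenitor genes 15 of 20 rose and 5 fell (camera adjusted p = 1.24e-11); ZIC1 rose (7.51 ± 0.18), as did PAX6 (4.56 ± 0.18) and SOX1 (5.59 ± 0.20), and SFRP1, a secreted WNT inhibitor, fell (-4.05 ± 0.09). The forebrain list was not called, since 6 of 13 rose and 4 fell (camera adjusted p = 0.758, not called), nor was the neuron list, since 11 of 22 rose and 3 fell (camera adjusted p = 0.120, not called). All pluripotency genes went down, in that 0 of 20 rose and 20 fell (camera adjusted p = 1.22e-27), with POU5F1 at -2.59 ± 0.06 and USP44 at -3.32 ± 0.08. All BMP targets went up, in that 13 of 13 rose and 0 fell (camera adjusted p = 3.71e-15), with BAMBI at 3.85 ± 0.10. For the WNT targets, 12 of 13 rose and 0 fell (camera adjusted p = 1.71e-17), with LEF1 at 7.27 ± 0.10. Of the FGF-ERK genes 12 of 15 rose and 1 fell (camera adjusted p = 7.91e-07). Among the cholesterol genes 15 of 15 rose and 0 fell (camera adjusted p = 1.45e-05). For the hypoxia and glycolysis genes, 2 of 16 rose and 14 fell (camera adjusted p = 9.64e-05, but adjusted p = 0.141 with an estimated correlation), with LDHA, lactate dehydrogenase, at -2.39 ± 0.12.

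PAX6 raised neural progenitor and neuron genes. SOX1 rose from 0.274 ± 0.0690 to 159.7 ± 7.56 CPM (9.14 ± 0.17), POU3F2, a factor of neural progenitors, from 0.559 ± 0.230 to 247 ± 9.18 CPM (8.78 ± 0.17), and NR2F2 from 0.155 ± 0.0760 to 113 ± 4.48 CPM (9.46 ± 0.12). MAP2, a microtubule protein gene of neurons, rose to 432 ± 14.3 CPM (4.35 ± 0.16) and DCX, a gene of migrating neurons, to 74.1 ± 7.12 CPM (2.95 ± 0.17). POU5F1 fell to 65.2 ± 7.07 CPM (-4.12 ± 0.07). NR2F1 reached 255 ± 3.01 CPM, a ratio of counts of 5505-fold (95% counting interval 1883 to 26696), and EN2 136 ± 1.75 CPM.

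Of the neural progenitor genes 15 of 19 rose and 4 fell (camera adjusted p = 1.51e-24). Among the neuron genes 21 of 22 rose and 1 fell (camera adjusted p = 7.51e-11), with STMN2 at 4.07 ± 0.13, ELAVL4 at 4.35 ± 0.18 and TUBB3 at 0.81 ± 0.10. For the forebrain genes, 11 of 13 rose and 2 fell (camera adjusted p = 7.28e-13). Of the midbrain and hindbrain genes 16 of 20 rose and 0 fell (camera adjusted p = 8.6e-09). All pluripotency genes went down, in that 0 of 20 rose and 20 fell (camera adjusted p = 9.55e-39), with LIN28A, an RNA-binding protein gene, at -2.25 ± 0.05. Among the surface ectoderm genes 2 of 9 rose and 6 fell (camera adjusted p = 0.0297, but adjusted p = 0.159 with an estimated correlation), with KRT19 at -2.50 ± 0.17 and PERP at -1.47 ± 0.06. For the hypoxia and glycolysis genes, 0 of 16 rose and 15 fell (camera adjusted p = 4.79e-09), with LDHA at -3.05 ± 0.12 and the glucose transporter gene SLC2A3 at -2.30 ± 0.07. Of the cholesterol genes 15 of 15 rose and 0 fell (camera adjusted p = 1.49e-06), with HMGCS1 at 1.88 ± 0.05. Among the BMP targets 13 of 13 rose and 0 fell (camera adjusted p = 8.18e-09). For the WNT targets, 10 of 13 rose and 1 fell (camera adjusted p = 3.69e-09). Of the FGF-ERK genes 9 of 15 rose and 1 fell (camera adjusted p = 5.66e-05). Among the notch genes 11 of 14 rose and 1 fell (camera adjusted p = 0.00329), with HEY1 at 4.61 ± 0.12. For the neural crest and placode genes, 12 of 17 rose and 5 fell (camera adjusted p = 0.0114); SOX10 fell (-4.99 ± 0.25) while PAX3 stood at 18.0 ± 0.198 CPM. In the mesenchyme list, 12 of 18 rose and 6 fell (camera adjusted p = 0.000268), with COL3A1 at 267 ± 10.4 CPM (at least 5759-fold). The endoderm list was not called, since 8 of 14 rose and 1 fell (camera adjusted p = 0.0752, not called), and SOX17 stood at 0.903 ± 0.0961 CPM.

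**Figure D3:**
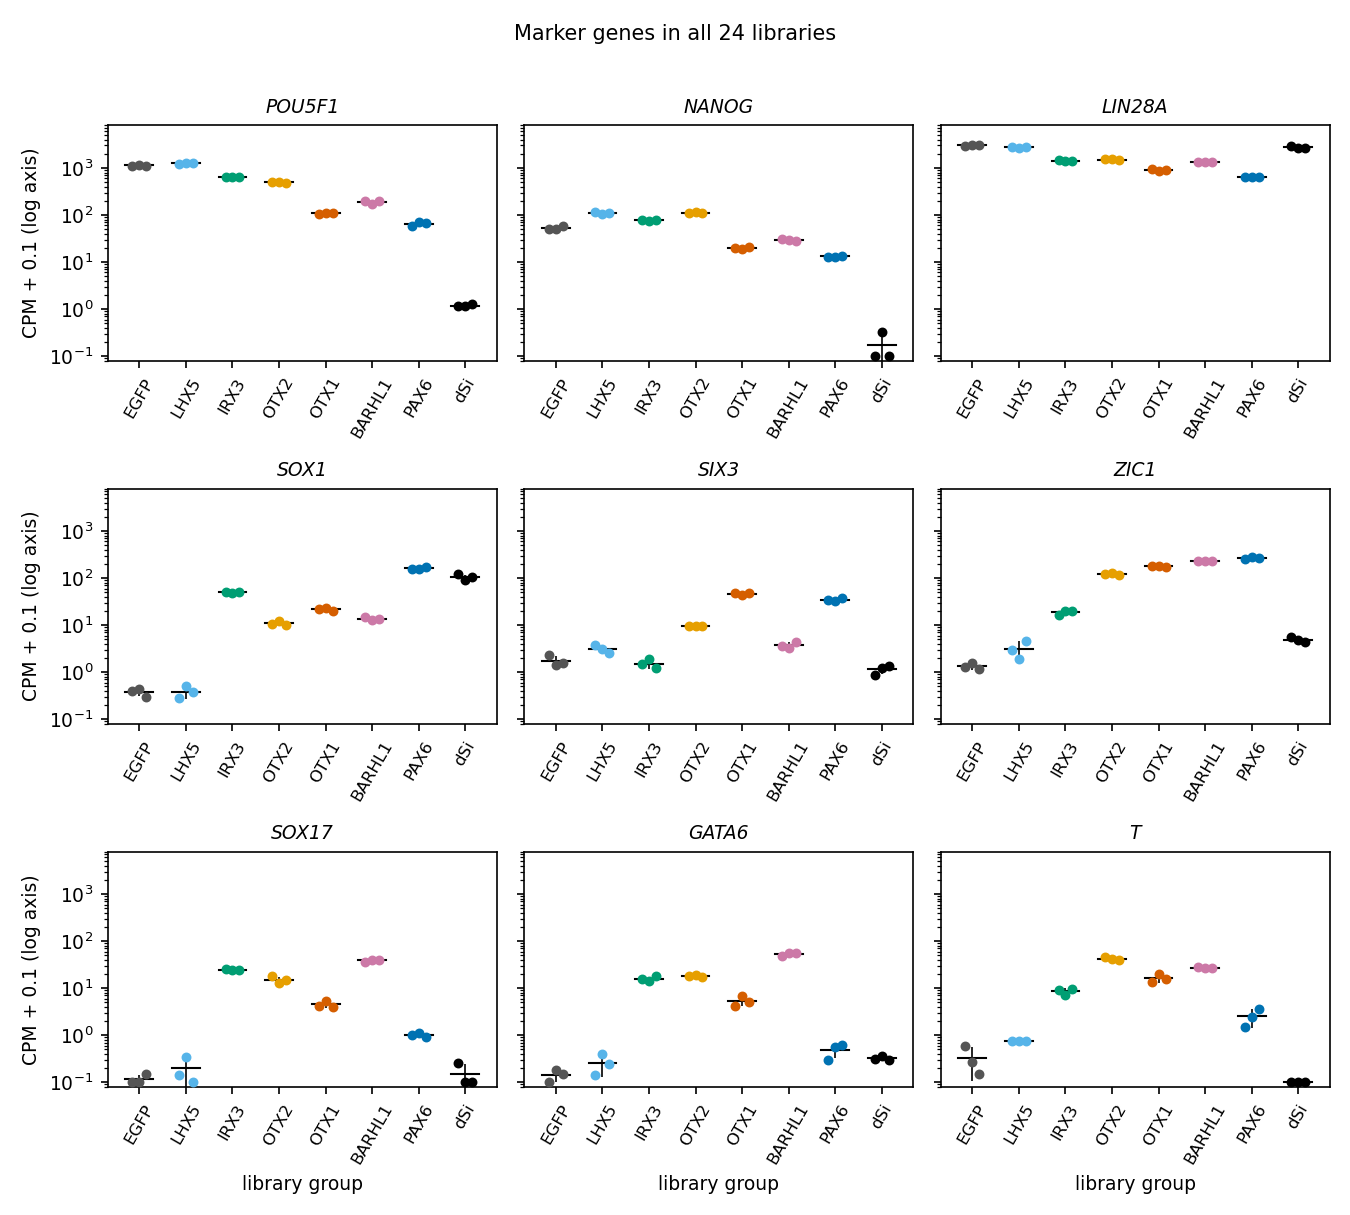
Levels of 9 marker genes in all 24 libraries, on a log axis of CPM plus 0.1, by group. Points are libraries, bars means and lines ± SD. POU5F1 runs from 1132 CPM in EGFP to 1.08 CPM in dSi, SOX1 from 0.274 CPM in EGFP to 159.7 CPM in PAX6, and SOX17 stands at 39 CPM in BARHL1 and 0.0519 CPM in dSi.

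In the dSi cells, which differed from EGFP cells also in medium, infection and time, TDGF1 (chromosome 3, 46616024 to 46623947, plus strand) had 0 counts against 765 ± 34.2 CPM in EGFP, at least 15765-fold lower. POU5F1 fell to 1.08 ± 0.0750 CPM (-10.02 ± 0.10), NANOG to 0.0753 ± 0.130 CPM (-9.27 ± 0.22) and CDH1, the epithelial cadherin, from 566 ± 8.37 to 0.0961 ± 0.0474 CPM (-12.43 ± 0.13). NR2F1 reached 332 ± 13.9 CPM, NR2F2 196 ± 5.99 CPM (10.26 ± 0.12) and SOX1 105 ± 13.3 CPM (8.53 ± 0.17). MSX1, a dorsal neural and crest gene, rose to 165 ± 55.5 CPM (9.44 ± 0.28) and WNT3A, a ligand of the dorsal midline, to 127 ± 30.4 CPM (8.72 ± 0.27). LIN28A, at 2759 ± 109 against 3030.4 ± 79.8 CPM, was called lower, and the call was lost without EGFP replicate 3 (adjusted p = 0.0640) or dSi replicate 3 (0.0571) and with only the compared groups in the fit (0.0876, the highest of its alternatives, the lowest being 2.94e-06).

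Among the pluripotency genes 0 of 20 rose and 19 fell (camera adjusted p = 4.91e-53). For the naive genes, 0 of 10 rose and 7 fell (camera adjusted p = 0.125, not called). Of the neural progenitor genes 17 of 20 rose and 2 fell (camera adjusted p = 9.45e-18), with MEIS2 at 7.44 ± 0.17 and NES, the neural intermediate filament gene, at 2.86 ± 0.07. PAX6 rose to 3.06 ± 0.868 CPM (1.40 ± 0.23) and ZIC1 to 4.83 ± 0.703 CPM (1.93 ± 0.22). Among the midbrain and hindbrain genes 13 of 20 rose and 2 fell (camera adjusted p = 9.13e-07), with PAX8 at 9.82 ± 0.20 and GBX2 at 7.28 ± 0.16. For the forebrain genes, 5 of 13 rose and 7 fell (camera adjusted p = 0.141, not called). The fall of SIX3 to 1.06 ± 0.251 CPM (-0.62 ± 0.23) was lost without EGFP replicate 1 (adjusted p = 0.188) or dSi replicate 1 (0.118) and with only the compared groups in the fit (0.0885), and the lowest of its alternatives was 0.00992. Of the neuron genes 8 of 22 rose and 8 fell (camera adjusted p = 0.802, not called), and DCX fell (-0.81 ± 0.20). Among the neural crest and placode genes 14 of 17 rose and 3 fell (camera adjusted p = 6.61e-08), with SNAI2 at 5.30 ± 0.12. In the mesenchyme list, 13 of 18 rose and 5 fell (camera adjusted p = 8.86e-05). Of the nodal targets 2 of 11 rose and 8 fell (camera adjusted p = 5.36e-07), with GDF3 at 0 counts (at least 165-fold lower) and FOXH1, the nodal cofactor, at -8.48 ± 0.23. GDF3, FOXH1 and TDGF1 are also members of the pluripotency list, so the nodal call is not separate from the fall of that list. Among the BMP targets 12 of 13 rose and 1 fell (camera adjusted p = 5.94e-08), with ID1 at 1.59 ± 0.15 and ID4 at 4.37 ± 0.09. For the WNT targets, 9 of 13 rose and 2 fell (camera adjusted p = 0.000661). Of the notch genes 10 of 14 rose and 1 fell (camera adjusted p = 0.0426, but adjusted p = 0.0659 with an estimated correlation). Among the proliferation genes 12 of 17 rose and 1 fell (camera adjusted p = 0.0426, but adjusted p = 0.171 with an estimated correlation). For the FGF-ERK genes, 9 of 15 rose and 4 fell (camera adjusted p = 0.0448, but adjusted p = 0.162 with an estimated correlation), and the latter calls were also lost with DESeq2 size factors (adjusted p = 0.0505 and 0.0527). Of the hypoxia and glycolysis genes 0 of 16 rose and 14 fell (camera adjusted p = 3.06e-05, but adjusted p = 0.131 with an estimated correlation). Among the cholesterol genes 7 of 15 rose and 4 fell (camera adjusted p = 0.629, not called). The first dSi library stood apart from the others, with an SD over genes of 0.530 (log2) from their mean against 0.144 between those, and without it 13161 genes changed in place of 12470. This library is part of the spread shared by all comparisons. With only the compared groups in the fit, 9703 genes changed in dSi, while the count was higher for each factor.

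**Figure D4:**
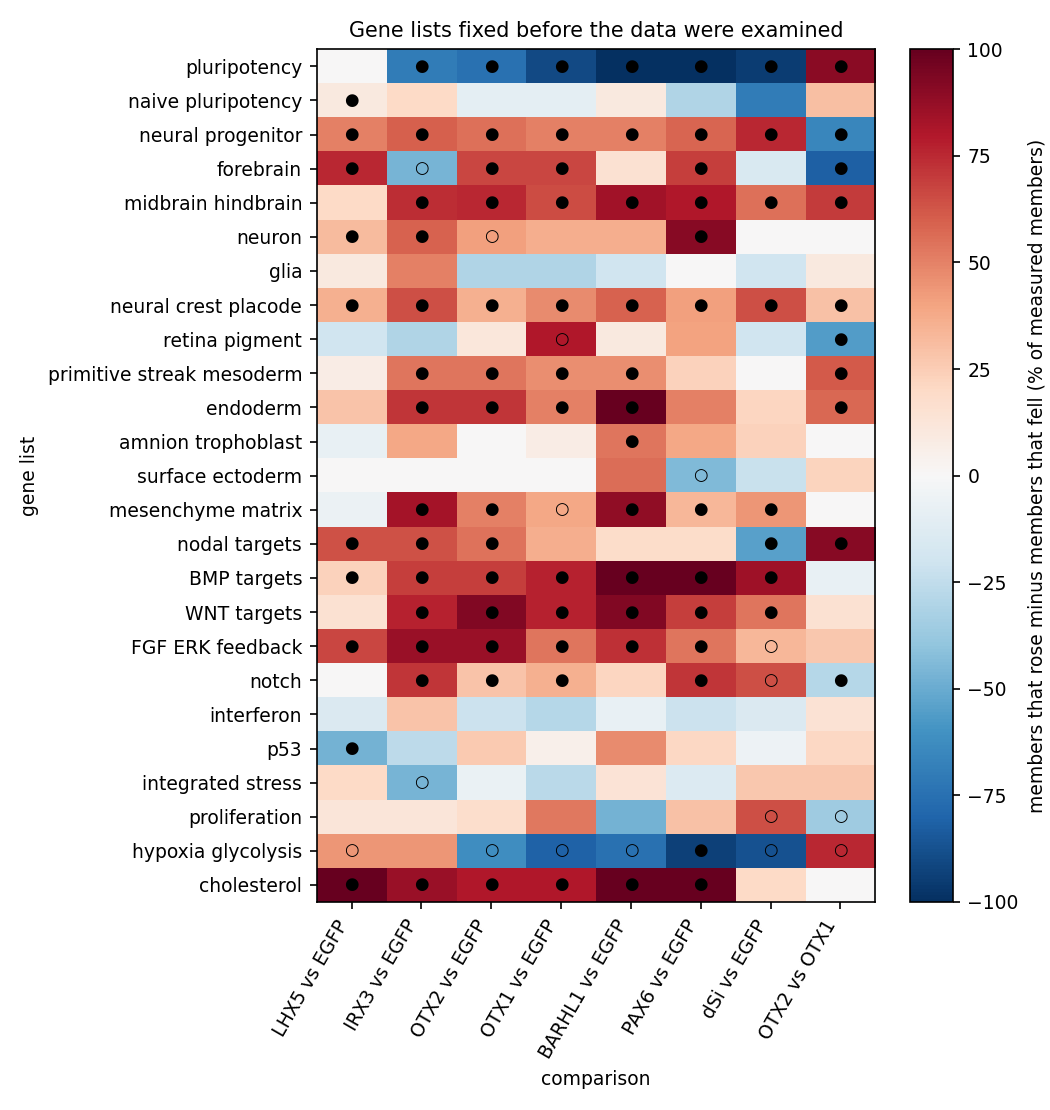
Balance of changed members, risen minus fallen as a percent of measured members, for 25 gene lists and 8 comparisons, from red (more rose) to blue (more fell). A filled circle marks a camera call that held with an estimated correlation and an open one a call lost with it, and the neural progenitor list was called up in all 7 comparisons with EGFP.

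Set directly against the OTX1 libraries, those of OTX2 had more pluripotency gene expression and less forebrain gene expression. OTX2 itself stood at 111 CPM in the OTX2 and 117 CPM in the OTX1 libraries, and OTX1 at 31.2 and 103 CPM. Differences between the 2 factors therefore cannot be told apart from differences in the amount of OTX transcripts. POU5F1 stood at 492 ± 12.2 CPM in OTX2 and 108 ± 3.68 CPM in OTX1 (log2 difference OTX2 minus OTX1 2.19 ± 0.06), and NANOG at 112 ± 4.75 and 20.1 ± 1.17 CPM (2.48 ± 0.10). HOXB1 (chromosome 17, 46605888 to 46608373, minus strand), a gene of the hindbrain and posterior mesoderm, stood at 9.12 ± 0.467 and 0.728 ± 0.0284 CPM (3.64 ± 0.21), and HOXB2 at 3.62 ± 0.23. ALDH1A1, an enzyme that makes retinoic acid, was lower in OTX2, at 4.79 ± 0.742 against 66.6 ± 7.76 CPM (-3.80 ± 0.15), as were FOXE3, a lens gene (-3.78 ± 0.36), and MITF (-3.03 ± 0.21). In all, 5565 of 17532 genes differed, 2911 higher and 2654 lower in OTX2, and with at least 2-fold as well 1078 were higher and 417 lower.

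In this comparison, where rose means higher in OTX2, of the pluripotency genes 18 of 20 rose and 0 fell, or 19 and 1 adjusted over the list alone (camera adjusted p = 3.1e-77). For the primitive streak genes, 8 of 13 rose and 0 fell, or 9 and 0 adjusted over the list alone (camera adjusted p = 1.24e-07). Of the endoderm genes 9 of 14 rose and 1 fell (camera adjusted p = 9.03e-05). Among the nodal targets 10 of 11 rose and 0 fell (camera adjusted p = 4.03e-19). MIXL1 stood at 2.03 ± 0.15, FOXA2, a factor of endoderm and floor plate, at 1.86 ± 0.12 and NODAL at 1.63 ± 0.13. For the midbrain and hindbrain genes, 15 of 20 rose and 1 fell, or 16 and 1 adjusted over the list alone (camera adjusted p = 1.23e-18). Of the neural crest and placode genes 9 of 17 rose and 4 fell, or 10 and 4 adjusted over the list alone (camera adjusted p = 0.00022). Among the hypoxia and glycolysis genes 12 of 16 rose and 0 fell (camera adjusted p = 4.14e-06, but adjusted p = 0.0842 with an estimated correlation). For the forebrain genes, 0 of 11 rose and 9 fell, or 1 and 9 adjusted over the list alone (camera adjusted p = 3.76e-27), with SIX3 at -2.29 ± 0.12 and LHX2 at -1.84 ± 0.10. Of the neural progenitor genes 3 of 20 rose and 16 fell (camera adjusted p = 1.18e-14), with DLK1 at -2.48 ± 0.10 and PAX6 at -1.84 ± 0.12. Among the retina and pigment genes 0 of 9 rose and 5 fell, or 0 and 6 adjusted over the list alone (camera adjusted p = 5.77e-06). For the notch genes, 2 of 14 rose and 6 fell (camera adjusted p = 0.00216). Of the proliferation genes 2 of 17 rose and 8 fell, or 2 and 9 adjusted over the list alone (camera adjusted p = 0.0243, but adjusted p = 0.143 with an estimated correlation).

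The mean of the 6 factors was also compared with EGFP, which can call a gene changed strongly in only some of them. NPTX1 fell to a mean of 2.72 CPM from 461 CPM (-7.59 ± 0.09), and IDO1 (-4.90) and GPR176 (-4.46) fell as well. MMRN1, which codes for a matrix protein of platelets and endothelium and had 0 counts in EGFP, stood at a mean of 69.4 CPM, at least 1519-fold higher, and NR2F1 at a mean of 101 CPM. Both differed widely between factors, MMRN1 from 0.635 ± 0.149 CPM in LHX5 to 132 ± 3.48 CPM in PAX6 and NR2F1 from 0.401 ± 0.196 to 255 ± 3.01 CPM. SOX2 fell in each of the 6 comparisons, to between 197 CPM in BARHL1 and 288 CPM in PAX6 from 512 ± 7.23 CPM. LIN28A fell in the mean of the 6 (-1.24 ± 0.03), while TUBB3 was not called (0.07 ± 0.08, adjusted p = 0.405). In the mean of the 6, 11633 of 17534 genes changed, 5939 up and 5694 down. This balance turned with the scaling, since with DESeq2 size factors in edgeR 5462 rose and 6143 fell, and with DESeq2 5579 rose and 6288 fell. Gene by gene, 1044 genes rose in all 6 comparisons and 974 fell in all 6, against 13.6 and 7.32 for independent lists, and 1498 changed in none, with TMM scaling. All 6 comparisons share the 3 EGFP libraries, so part of this excess may come from them, and genes changed in all 6 cannot be separated from something particular to the EGFP cells. The F test between the 6 factors, which does not use EGFP, found differences in 15372 of 17534 genes, among them POU5F1, NANOG, SOX1, SIX3, ZIC1 and SOX17 (adjusted p = 2.19e-22, 6.94e-18, 1.75e-21, 8.87e-19, 2.78e-19 and 2.11e-17).

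The factors also changed each other's genes. PAX6 rose in the OTX1 libraries to 64.8 ± 2.71 CPM (5.80 ± 0.17), in BARHL1 to 27.4 ± 1.43 CPM and in OTX2 to 18.1 ± 1.63 CPM. LHX5 rose in OTX1 to 70.0 ± 4.73 CPM (5.37 ± 0.13), in OTX2 to 37.3 ± 1.11 CPM, in PAX6 to 26.1 ± 2.09 CPM and in BARHL1 to 7.4 ± 0.547 CPM. It fell in IRX3 to 0.849 ± 0.127 CPM. OTX1 rose in PAX6, OTX2, BARHL1 and LHX5 libraries (37.8 ± 3.42, 31.2 ± 3.13, 24 ± 1.66 and 18.3 ± 1.68 CPM) and fell in IRX3 (0.535 ± 0.0732 CPM). IRX3 rose in PAX6 to 39.4 ± 2.61 CPM and in BARHL1 to 6.51 ± 0.882 CPM, and fell in LHX5 to 1.59 ± 0.231 CPM. OTX2 rose in OTX1 and PAX6, fell in IRX3 to 29.3 ± 1.68 CPM and in LHX5 to 39.5 ± 1.58 CPM, and was not called in BARHL1 at 59.97 ± 3.40 CPM (adjusted p = 0.687). BARHL1 rose in OTX2, OTX1 and PAX6 from 0.0762 ± 0.0728 CPM but stayed low, at 1.67 ± 0.291, 0.684 ± 0.129 and 0.551 ± 0.192 CPM. With edgeR p-values adjusted over these 30 tests, 18 rose and 6 fell. Over all genes, 70.5% were called in BARHL1, 55.3% in IRX3, 32.5% in LHX5, 67.1% in OTX1, 59.9% in OTX2 and 72.1% in PAX6. Many calls would thus be met in any set of genes, and the count alone is no sign of regulation between these factors. The fall of BARHL1 in IRX3 to 0 counts, counted among the 6, rests on 3, 2 and 0 counts in the EGFP libraries, so the groups overlap. Its call was lost without EGFP replicate 1 (adjusted p = 0.0857), and the lowest of its alternatives was 0.00612.

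To ask how far each factor moved genes the way dSi did, the calls they shared were counted. The dSi cells differed from EGFP cells also in medium, infection and time, and their changes include the fall of pluripotency genes. Shared calls therefore do not measure neural induction alone. Of the genes that rose at least 2-fold in dSi, BARHL1, which raised mesenchyme and endoderm genes, shared 66.5%, beside 67.1% in OTX1. In PAX6, 9279 genes changed in the same direction as in dSi, 4805 up and 4474 down, and 849 in the opposite one. Here too the balance turned, with 4439 up and 4787 down under DESeq2 size factors and 4429 up and 4846 down with DESeq2. The same counts were 9222 and 555 in OTX1, 8643 and 1085 in BARHL1, 8346 and 582 in OTX2, 6328 and 1441 in IRX3, and 3406 and 1358 in LHX5. For independent lists, the shared numbers up and down would be 2441 and 2061 in PAX6, 2328 and 1869 in OTX1, 2427 and 1977 in BARHL1, 2153 and 1604 in OTX2, 1950 and 1509 in IRX3, and 1153 and 881 in LHX5. Of the genes that rose at least 2-fold in dSi, 71.6% also did in PAX6, 67.1% in OTX1, 66.5% in BARHL1, 54.4% in OTX2, 48.8% in IRX3 and 11.7% in LHX5. Over all genes, the shares that rose at least 2-fold were 16.6%, 14.1%, 16.5%, 11.6%, 11.5% and 3.70% in the same order. Of the genes that fell at least 2-fold in dSi, 71.3% also did in PAX6, 68.3% in OTX1, 60.04% in BARHL1, 52.2% in OTX2, 32.3% in IRX3 and 14.3% in LHX5. Over all genes, 18.6%, 16.2%, 15.5%, 12.1%, 7.69% and 4.31% fell at least 2-fold. Across genes, which are not independent replicates, the log2 changes of dSi correlated with those of OTX1 at r = 0.780, PAX6 at 0.772, OTX2 at 0.697, BARHL1 at 0.672, IRX3 at 0.582 and LHX5 at 0.317, against 0.164 to 0.192 in the simulations. The covariances were 2.83 in PAX6, 2.60 in OTX1, 2.44 in BARHL1, 2.01 in OTX2, 1.48 in IRX3 and 0.50 in LHX5, against 0.0139 to 0.0169 in the simulations. The simulations drew each group around the mean of the EGFP libraries, so they leave out the error of that mean, which all comparisons share. Their values are too low a baseline for a shared control. How far the smaller values, such as those of LHX5, lie above a full baseline cannot be told. NR2F1, NR2F2 and PAX3 rose and TERF1 and SOX2 fell in dSi and in all 6 factors. Unchanged groups simulated in this way shared 0 calls, a value that also leaves out the error of the EGFP mean. It does not apply where both comparisons hold effects. The 3 EGFP libraries were not split, since 1 part would have held a single library, so part of the excess over independent lists may come from them.

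**Figure D5:**
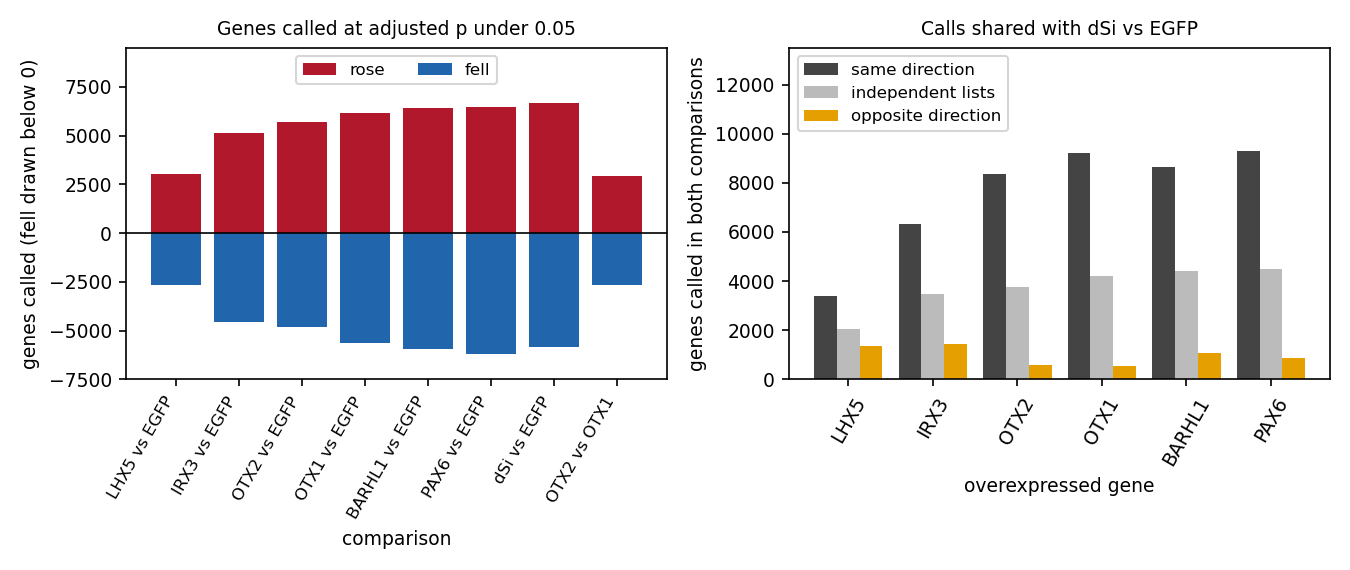
Left, numbers of genes that rose and fell with TMM scaling in each of 7 comparisons with EGFP and in OTX2 against OTX1. More rose than fell in all of these, which turned in the 7 comparisons with EGFP under DESeq2 size factors in edgeR. Right, for each factor, the numbers of genes changed in the same direction as in dSi, the number for independent lists and the number changed in the opposite direction, with 9279 shared in PAX6 and 3406 in LHX5.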

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

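In this part, the tests on the first dSi library, the label exchange of OTX1 and OTX2, the scaling test of the ribosomal protein genes and the counts of other splits were chosen only after the results were seen, and the test for undifferentiated cells replaced an earlier one after its values were seen.

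NANOG and ID1 moved in opposite directions in the OTX1 and OTX2 libraries, and the difference itself was tested with edgeR. They were picked from the marker panel and the factor genes as those called in opposite directions against EGFP with the direct difference called as well. A called difference was thus a condition for naming them and not a separate check. NANOG, a core pluripotency factor, fell with OTX1 (-1.41) and rose with OTX2 (1.07), a difference of 2.48 ± 0.10 on the log2 scale (adjusted p = 3.05e-14, with the 3 OTX2 libraries above the 3 OTX1 libraries). ID1, a target of BMP signalling, rose with OTX1 (0.56) and fell with OTX2 (-0.39), a difference of -0.95 ± 0.15 (adjusted p = 3.72e-05). Over all alternatives the difference of NANOG ran from 2.44 to 2.52 and that of ID1 from -1.02 to -0.87, while the fall of ID1 with OTX2 was lost without any 1 of the EGFP or OTX2 libraries (adjusted p = 0.0511 to 0.0981). The ID1 levels of the OTX2 and EGFP libraries did not overlap (34.3 to 37.4 and 46.4 to 49.4 CPM).

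The first dSi library stood apart from the other 2, with an SD of the log2 difference of 0.530 over 10595 genes, against 0.144 between the others. Its difference fell with transcript length, from a median of 0.78 for transcripts up to 1000 bases to -0.65 over 8000 bases, and the length trend held 48.0% of the variance. Removing it left an SD of 0.382, removing the GC trend left 0.508 and removing both left 0.377, so neither trend accounts for the whole difference. Undifferentiated cells in that library are argued against by POU5F1 at 0.0918% and the long noncoding ESRG at 0.0189% of the EGFP level, with TDGF1 at 0. A library preparation that favoured short transcripts may account for part of it, and a difference between the cultures stays open, since no batch is labelled.

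OTX2 counts were no higher in the OTX2 than in the OTX1 libraries, at 111 and 117 CPM. An exchange of the 2 groups' labels is argued against by OTX1, which was lower in the OTX2 libraries (31.2 against 103 CPM, -1.72 ± 0.10). Reads of OTX1 counted for OTX2 are argued against by the sequences, since of 4917 windows of 50 bases in OTX1 transcripts 0, or 0%, lay in an OTX2 transcript with at most 2 mismatches. The labels name no OTX2 virus for the OTX1 libraries, where OTX2 stood at 117 ± 4.78 against 61.5 ± 4.06 CPM in EGFP (0.93 ± 0.07). With the sequences, this points to a rise of the cells' own OTX2 in those libraries. In the OTX2 libraries the counts do not separate introduced from own copies, so a weak OTX2 construct stays open.

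Genes of ribosomal proteins, a group chosen after the data were seen, were lower than in EGFP in BARHL1, OTX1 and PAX6, with medians over 77 genes of -0.85, -0.56 and -0.86. After a length trend fitted on the other genes was removed, the medians were -0.83, -0.39 and -0.59 (-0.585), and after a GC trend -1.09, -0.60 and -0.94. Neither trend alone accounts for the falls in BARHL1 and PAX6, while length accounts for part of those in OTX1 and PAX6. With DESeq2 size factors the medians were -0.88, -0.60 and -0.90. These factors moved the median of all genes by only -0.04 in BARHL1 and -0.04 in PAX6. They could not have removed falls of this size, so the test does not decide whether scaling plays a part. A lower share of ribosomal protein transcripts in these cells may be the reason, but reads shared with their many pseudogenes were not tested and stay open.

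Other splits of the same libraries were fitted in the same way with edgeR. For the comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. In each, 1 of 10 splits, the real one, gave as many genes: 12354 in BARHL1, 9688 in IRX3, 5693 in LHX5, 11770 in OTX1, 10510 in OTX2, 12646 in PAX6 and 5565 in OTX2 against OTX1, each with 0 as the highest other, and 12470 in dSi with 654 as the highest other. For the mean of the 6 factors, 1 of 40 splits gave 11633 genes and the highest other 4813, and for the differences among the 6 factors 1 of 40 gave 15372 and the highest other 6075. The median of the other splits was 0 for both. Splits that mix groups widen the spread within them, so they call fewer genes whenever the libraries of a group are alike. These counts therefore show only that libraries of a group resemble each other, and they do not exclude chance. Libraries of a group may come from 1 culture, so chance differences between cultures stay open.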

How the results depend on the processing

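Row handling, with all copies as deposited or copies summed, was an alternative chosen after seeing the data, and all others were chosen before the data were examined. All 18 counts of changed genes, shared calls, cross-regulated genes and called lists stayed within 1.5 times under every alternative run. LHX5 ranged from 5292 without the low-count filter to 7612 with only the compared groups in the fit, dSi from 9703 with only the compared groups to 13093 with all copies, and OTX2 against OTX1 from 5105 to 6408. With single libraries left out, LHX5 ranged from 4688 to 4865 and dSi from 11914 to 13161, and calls shared between LHX5 and dSi reached 4658 without dSi replicate 1. With the replicate number as a block, 12343 genes changed in BARHL1, 9725 in IRX3, 5694 in LHX5 and 12476 in dSi. Replicate numbers gave no pairing across all groups, since 84 correlations between equal numbers had a median of -0.0019, but 16 were over 0.1, and for OTX1 and dSi all 3 were (0.625, 0.378 and 0.427). These 3 are not independent, since they compare deviations from the group mean and replicate 1 stood apart in both groups. Its pairs had a chi-square per degree of freedom of 8.68 and 7.48 in OTX1, against 2.67 for the other pair. In dSi the values were 88.0 and 81.2 against 2.67. A resemblance of the first replicates alone could give all 3. With the block, OTX1 and dSi shared 9251 calls in place of 9222.

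Of 109 list calls, 93 held with an estimated correlation, 107 with DESeq2 size factors and 106 with the block, which ended those of naive pluripotency in LHX5 (adjusted p = 0.0627), retina and pigment in OTX1 (0.0640) and FGF-ERK feedback in dSi (0.0556). Of 707 values of named genes, DESeq2 kept 706 on their side of the threshold and DESeq2 size factors 706, and of 4827 values with a library left out 4792 stayed, 32 lost and 3 gained a call. No call of a named gene or list reversed, and the cause of these changes was not tested. DESeq2 size factors moved the median of all genes by -0.01 in OTX2 against OTX1 to -0.07 in dSi. With them falls outnumbered rises in all 7 comparisons with EGFP, in the mean of the 6 factors and in the calls each factor shared with dSi, where rises were more with TMM factors. In data simulated for LHX5 against EGFP only, at their depth and with few changed genes, edgeR called 100% of genes changed by 1 on the log2 scale, 50% at 0.5 and 8% at 0.25. The changed genes there stood above a minimum level in EGFP, so these shares do not cover weakly expressed genes.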

Other observations

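The groups of genes in this part and their values were chosen only after the data were seen. HOX genes, which pattern the body axis, were summed over the 31 that passed the filter on counts, many of which had almost no counts outside the BARHL1 libraries. The filter therefore fixed much of which genes were measured, and numbers of called HOX genes are not compared between the factors. The genes of paralogue groups 1 to 4, active from the hindbrain on, summed to 159.7 ± 8.74 CPM in BARHL1, 60.6 ± 2.72 in OTX2, 6.65 ± 0.612 in OTX1, 4.35 ± 0.228 in IRX3, 3.43 ± 0.588 in PAX6, 0.201 ± 0.186 in dSi, 0.0637 ± 0.0313 in LHX5 and 0.0492 ± 0.0496 in EGFP. Those of groups 5 to 13, active in the trunk, summed to 234 ± 36.5 CPM in BARHL1, 1.14 ± 0.261 in OTX2, 0.179 ± 0.0385 in dSi, 0.130 ± 0.0231 in IRX3, 0.0952 ± 0.124 in LHX5, 0.0593 ± 0.0643 in OTX1, 0.0301 ± 0.0262 in PAX6 and 0.0139 ± 0.0241 in EGFP.

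Metallothionein genes, which code for metal-binding proteins, summed to 199.99 ± 35.5 CPM in EGFP, 188 ± 12.1 in LHX5, 161 ± 17.4 in IRX3, 64.9 ± 1.88 in OTX2, 32.3 ± 2.95 in BARHL1, 27.1 ± 3.60 in OTX1, 15.2 ± 1.06 in PAX6 and 12.1 ± 4.36 in dSi. All 7 measured genes fell in BARHL1, OTX1, OTX2, PAX6 and dSi, 4 fell in IRX3, and in LHX5 2 rose and 2 fell, with the same numbers under DESeq2 size factors. In OTX2 against OTX1, all 7 were higher.

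Ribosomal protein genes summed to 84906 ± 1111 CPM in EGFP, 83109 ± 27886 in dSi, 80963 ± 3325 in LHX5, 70908 ± 1384 in IRX3, 62653 ± 1467 in OTX2, 57955 ± 3197 in OTX1, 46979 ± 44.5 in BARHL1 and 46203 ± 1226 in PAX6. Of 77 genes, 77 fell in BARHL1 and in PAX6, 72 in OTX1 (75 with DESeq2 size factors), 64 in OTX2 (68), 27 in IRX3 (40) and 0 in LHX5 (0), and in dSi 3 rose and 5 fell (1 and 9). The median of these genes against EGFP was 0.50 in the first dSi library and -0.30 in each of the others.

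The factors with the highest level of their own gene had the fewest changed genes: LHX5 stood at 555 CPM with 5693 genes and IRX3 at 456 CPM with 9688, against 111 CPM and 10510 genes in OTX2, 103 CPM and 11770 in OTX1, 77.0 CPM and 12646 in PAX6, and 46.3 CPM and 12354 in BARHL1. No correlation was computed over these 6 values. They are levels of different genes, not scaled for transcript length, and each holds introduced and own copies, with OTX2 at 61.5 CPM already in EGFP. The order therefore does not rank the amounts of the introduced genes.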
